A study of Mus musculus with 4 samples.

How the data were processed

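RNA sequencing was carried out on RAW264.7 cells, a mouse macrophage-like cell line, after 24 h with lipopolysaccharide (LPS), a bacterial cell wall component that activates macrophages. The labels put 2 libraries in the group shMettl3, in which Mettl3 was knocked down with a short hairpin RNA, and 2 in the control group shNC. Each library came from total RNA prepared with a TruSeq RNA kit, per the labels' protocols. No unstimulated cells were among the samples, so nothing below measures the response to LPS itself. The labels do not say whether the replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

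The deposited table gave 15421 genes with 3 values per library, per the file headers: FPKM, TPM and a read count. The submitters' processing notes name Bowtie 0.12.2 and the mm9 build, without saying what each was used for. The program that counted the reads, its annotation and its filters are not given in the sources used here. The deposited TPM had the same sum in each library within rounding, and the FPKM of a library was its TPM times a constant. About 9% of the deposited read counts were not whole (9.17% to 9.37% per library), as is usual for estimated counts, in which a read that matches several genes is shared out between them. The estimated counts were therefore taken as not normalized, and were rounded to whole numbers before testing. Every per-sample column of the table was used or matched to a library. Gene symbols and Entrez identifiers are those of the file. No annotation of mm9 was used here, and no coordinates are given.

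The design written before the data were examined assumed FPKM alone, tested with limma on log2(FPKM + 1), and named edgeR's quasi-likelihood test for a file that held counts. Because the file held estimated counts, edgeR 4.0.16 in R 4.3.3 was the main test (TMM scaling, glmQLFit and glmQLFTest, 2-sided, Benjamini-Hochberg adjustment, threshold 0.05), and limma 3.58.1 became an alternative. Genes with a mean FPKM of at least 1 over the 4 libraries were tested, which left 10291. Normalized counts are given as CPM, computed by edgeR with TMM-scaled library sizes. Log2 fold changes are shMettl3 minus shNC, and their standard errors (SE) were taken from the fold change and the quasi-likelihood F statistic. Mettl3 was set beforehand as a single result and is judged by its unadjusted p.

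Totals of estimated counts per library ran from 16608092 to 17102478, and 1 count corresponded to 0.0585 to 0.0602 CPM before TMM scaling. Counting error was therefore small for most of the named genes, and the spread between libraries set the precision. The biological coefficient of variation was 33.6%. The kit and the notes do not say whether counting used the strand, so overlapping and antisense genes cannot be separated. Values of related or near-identical genes (Ccl3 and Ccl4, the Oas and Ifit families, histones, Lyz1 and Lyz2, ribosomal protein genes with their pseudogenes) depend on how any shared reads were divided. They are uncertain to the extent that reads were shared, which was not measured.

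32 gene lists were fixed before the data were examined: m6A writers and erasers, m6A readers, inflammatory cytokines, chemokines, inflammatory effectors and activation markers, the NF-kB pathway, TLR4 signalling, interferon-stimulated genes, antigen presentation, feedback inhibitors of inflammatory signalling, inflammasome and pyroptosis, alternative activation markers, macrophage identity, osteoclast differentiation, glycolysis and hypoxia, oxidative phosphorylation, cholesterol and fatty acid synthesis, cholesterol efflux and lipid storage, G1/S and DNA replication, G2/M and mitosis, p53 targets, the integrated stress response and amino acid supply, endoplasmic reticulum stress, NRF2 antioxidant genes, lysosome and autophagy, apoptosis regulators, immediate early genes, cytosolic ribosomal proteins, splicing factors, nucleolar RNA host and nuclear retained RNAs, replication-dependent histones, and markers of other cell types. The 30 lists with at least 5 tested members were tested with limma's camera, which compares a list with the other genes, with a preset correlation between genes of 0.01 and again with the correlation estimated for each list. Adjustment was over the 30 lists. With an estimated correlation, camera also takes its degrees of freedom from the few libraries and not from the genes. A call lost in that test therefore need not be lost through correlation. For the alternative activation list, with an estimated correlation of −0.102, camera's unadjusted p went from 0.0152 to 0.128.

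Named genes followed a rule fixed beforehand. It took the members of the list of m6A writers and erasers. It also took up to 12 genes per direction past the threshold or, where none passed, the 6 with the smallest unadjusted p, leaving out provisional symbols. In each list it took up to 4 called members or, where none was called, the 2 with the smallest unadjusted p. Other genes are named as chosen after their values were seen.

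The fit was tested on simulated data for this comparison. In each simulation 200 genes were changed, besides the members of a list shifted 2-fold. With the dispersions estimated from the 4 libraries (10291 genes), 2.99% of 2-fold, 63.6% of 4-fold and 89.6% of 8-fold changes passed, with 19 false calls. With the fitted gene-to-gene spread of the dispersion (10289 genes), no change of 2, 4 or 8-fold passed, although 92.3% of the 8-fold changes had an unadjusted p under 0.05. With a coefficient of variation of 10% (10291 genes), 95.7% of 2-fold changes and 100% of the larger ones passed, with 14 false calls. The simulation with the gene-to-gene spread was added after the results were seen. In all 3 simulations camera with the preset correlation passed a list shifted 2-fold and did not pass a list that was not shifted. The simulated genes varied independently of each other, and no effect shared by same-numbered libraries was simulated. These simulations therefore do not show how often camera falsely calls a list of correlated genes.

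The alternatives were limma on log2(FPKM + 1), log2(FPKM + 0.1) and log2(FPKM + 0.5), with and without a variance trend or a robust prior, quantile normalization, median-of-ratios scaling, total-count scaling, no filter, a mean FPKM of at least 5, a 2-fold minimum, a block for the replicate number, DESeq2 1.42.0, camera with an estimated correlation, and leaving out each library in turn. Of these, total-count scaling was added after the data were seen, and limma on log2(FPKM + 1), the test first planned, was then made an alternative. A fit without 1 library sets libraries numbered 1 and 2 against a lone library of a single number. Its fold changes therefore also move with anything that same-numbered libraries share.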

Results

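The transcriptomes of LPS-activated RAW264.7 macrophages with and without knockdown of Mettl3 were compared. Mettl3 encodes the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA. The series held 4 libraries, 2 from cells with a hairpin against Mettl3 (shMettl3) and 2 from cells with a control hairpin (shNC), all taken after 24 h of LPS. The totals were 16858388 and 16608092 estimated counts in the shMettl3 libraries and 17102478 and 16732676 in the shNC libraries. The 10 most abundant genes held 7.51% to 8.99% of the counts of a library. Between 13343 and 13769 of the 15421 genes had a count in a given library, and 416 had none in any library.

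Mettl3 transcripts (Entrez 56335) were lower in both knockdown libraries. The TMM-normalized CPM were 9.60 and 8.98 in shMettl3 against 26.7 in both shNC libraries, or 9.29 ± 0.440 against 26.7 ± 0.0326 (SD, n = 2 each). The deposited FPKM were 4.99 and 4.59 against 14.32 and 12.75. The knockdown libraries thus held 34.8% of the control level, a log2 fold change of −1.52 (SE 0.284, 95% interval −2.22 to −0.82). This result was set beforehand, and edgeR's quasi-likelihood test gave it an unadjusted p of 0.00185, while its adjusted p over all genes was 0.304 (0.00206 in DESeq2). An exact permutation of 2 against 2 libraries cannot give a p below 0.333.

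The other m6A writers and erasers had no adjusted p under 0.05 in edgeR's test. Alkbh5, an m6A demethylase, had 129 ± 15.8 normalized CPM in shMettl3 and 254 ± 87.9 in shNC (SD, n = 2 each), a log2 fold change of −0.98 (SE 0.336, adjusted p = 0.431). Mettl16, another RNA methyltransferase, had 40.2 ± 0.206 against 27.3 ± 0.837 (log2 fold change 0.56, SE 0.234, adjusted p = 0.510). Rbm15b, a subunit of the writer complex, had a log2 fold change of 0.57 (SE 0.323). The log2 fold changes of Mettl14, the partner of Mettl3 in the catalytic core, Wtap, Virma, Cbll1, Zc3h13, Rbm15 and the demethylase Fto lay between −0.30 and 0.27. Those of Mettl14, Wtap, Virma, Cbll1 and Fto changed sign under some settings. Alkbh5 was at −0.56 without shNC replicate 2, and Rbm15b at 0.32 without shNC replicate 1 and 0.94 without shNC replicate 2. Zc3h13 was at −0.62 without shMettl3 replicate 1 and −0.04 without shMettl3 replicate 2, and Rbm15 at 0.0034 without shNC replicate 1 and 0.38 without shNC replicate 2. Adjusted over the list alone, 1 of the 11 members, Mettl3, was lower, against 2 in DESeq2 and 0 in each fit that left out 1 of the 4 libraries. The list as a whole was not called by camera (adjusted p = 0.567). Among the 11 tested m6A readers, Elavl1 had a log2 fold change of 0.42 (SE 0.232) and Ythdf3 −0.51 (SE 0.363; −0.87 without shNC replicate 1 and 0.0562 without shNC replicate 2). The readers were not called either (median 0.11, adjusted p = 0.726).

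The question of the main comparison was which transcripts differ between knockdown and control cells under LPS. The genes with the smallest unadjusted p on the higher side were Stap1, Csf3, Ltb, Urah, Calcrl and Mybl2. Csf3, which encodes the granulocyte growth factor G-CSF, had 286 ± 87.1 normalized CPM in shMettl3 and 43.1 ± 5.95 in shNC (SD, n = 2 each), a log2 fold change of 2.73 (SE 0.339). Stap1, a signalling adaptor, had 366 ± 48.5 against 67.6 ± 9.61 (2.44, SE 0.290), and Calcrl, the calcitonin receptor-like receptor, had 286 ± 39.6 against 59.4 ± 11.4 (2.27, SE 0.298). Ltb, which encodes lymphotoxin beta, had 23.5 ± 5.32 against 2.80 ± 0.572 (3.06, SE 0.392). Mybl2, a transcription factor of cell cycle genes, had 28.7 ± 9.80 against 3.82 ± 0.182 (2.91, SE 0.384). Urah had 252 and 122 counts in shMettl3 and only 4 and 1 in shNC, so its log2 fold change of 6.10 (SE 0.794) rests on very few control reads.

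On the lower side these were Chchd10, Mreg, Tspan10, Aph1c, Atp11a and Gyg. Chchd10, a mitochondrial protein gene, had 14.5 ± 2.88 normalized CPM in shMettl3 and 144 ± 1.13 in shNC, a log2 fold change of −3.31 (SE 0.282). Mreg, melanoregulin, had 7.62 ± 1.12 against 46.4 ± 4.91 (−2.60, SE 0.285), and Tspan10, a tetraspanin, 12.8 ± 1.38 against 62.0 ± 4.34 (−2.28, SE 0.255). Aph1c, a gamma-secretase subunit, had 19.5 ± 2.45 against 80.7 ± 0.602 (−2.05, SE 0.248). Atp11a, a phospholipid flippase, had 97.2 ± 21.5 against 471 ± 27.7 (−2.28, SE 0.298). Gyg, glycogenin, had 165 ± 15.1 against 554 ± 3.87 (−1.75, SE 0.260).

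None of these 12 genes passed the threshold in edgeR's quasi-likelihood test, their adjusted p running from 0.275 to 0.304, although in each of them both knockdown libraries lay on one side of both controls. Over the 10291 genes tested, edgeR called 0 genes higher and 0 lower at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 558 higher and 473 lower genes, 1031 in all. If no gene differed, 514.55 would be the average number. Of the other 2 splits of the 4 libraries into pairs, that by replicate number gave 666 and the remaining one 64. In both, any difference from the knockdown lies within the pairs, so neither shows what no difference would give. DESeq2 called 211 genes higher and 123 lower, the 12 genes among them, and limma on log2(FPKM + 1) called 0. Without the filter on low values edgeR called 1 gene, Chchd10 (adjusted p = 0.0324). Both knockdown libraries lay above both controls for 2147 genes and below for 2268, together 42.9% of the genes tested where chance gives 33.3%. Across genes, the closest 2 libraries were shMettl3 replicate 1 and shNC replicate 1 (Pearson r = 0.958 of log2(FPKM + 1)), closer than the libraries within shMettl3 (0.951) or within shNC (0.946). The most distant were shMettl3 replicate 1 and shNC replicate 2 (0.896). Genes are not independent replicates, and no library duplicated another, since replicates differed by far more than counting noise (chi-square per degree of freedom 119 and 126).

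**Figure D1:**
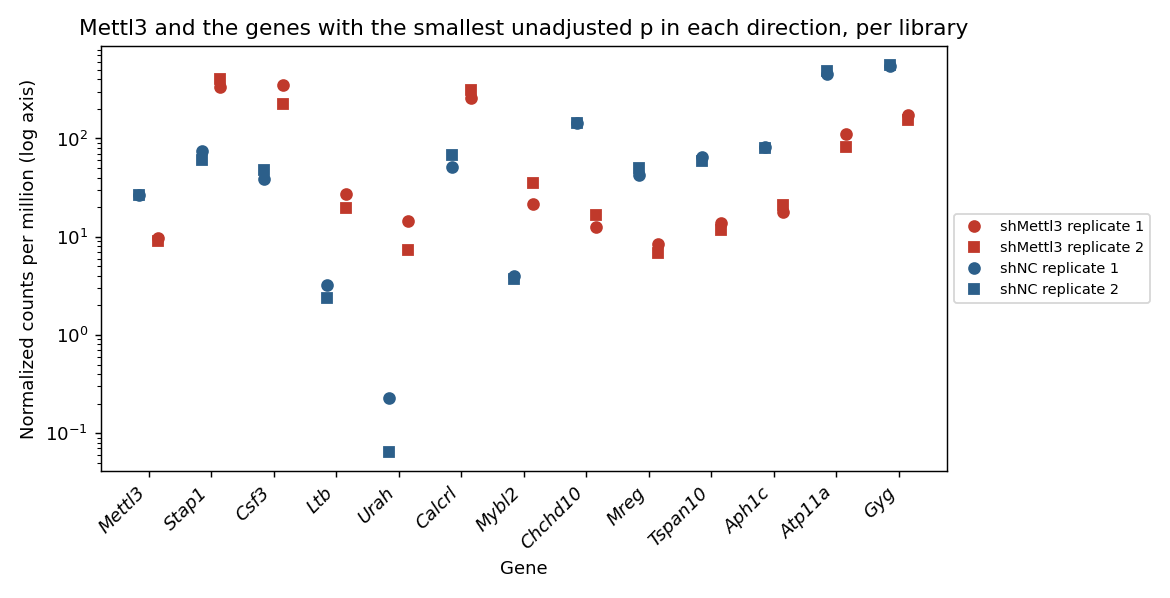
Normalized CPM (log axis) of Mettl3 and the 6 genes in each direction with the smallest unadjusted p, 1 point per library, with shMettl3 in red, shNC in blue, circles for replicate 1 and squares for replicate 2. Mettl3 lies at 9.60 and 8.98 in the knockdown libraries and at 26.7 in both controls, and for each gene shown the points of the 2 groups do not overlap.

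Cell cycle genes stood highest among the lists. Of the 35 tested genes of G2/M and mitosis, 35 had a positive log2 fold change, with a median of 2.79, or 6.89-fold. Adjusted over the list alone, 34 were higher in shMettl3 and 0 lower, while 0 passed over all genes in edgeR's test and 29 in DESeq2. Ccna2, which encodes cyclin A2, had 18.0 and 52.4 normalized CPM in shMettl3 against 3.09 and 2.14 in shNC (log2 fold change 3.75, SE 0.609). Mki67, the proliferation marker Ki-67, had 81.2 and 146 against 21.6 and 11.01 (2.80, SE 0.465). Camera called the list higher (adjusted p = 2.5e-49). With the correlation estimated (0.858 between its genes), camera's adjusted p was 0.674, in a test with few degrees of freedom here. Without shNC replicate 2, the median was 2.40 and the call held, but 0 of the 35 genes passed over the list alone, and without shMettl3 replicate 2 there were 22.

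Of the 35 tested genes of G1/S and DNA replication, 33 had a positive log2 fold change (median 1.68, 3.20-fold), and 27 were higher when adjusted over the list alone, with 0 over all genes in edgeR's test and 17 in DESeq2. Mcm5 and Mcm4, subunits of the replicative helicase, had 82.8 ± 27.2 against 11.2 ± 4.13 and 59.4 ± 10.1 against 14.6 ± 4.44 normalized CPM (log2 fold changes 2.88 and 2.02, SE 0.4 and 0.322). Camera called the list higher (adjusted p = 3.37e-35; adjusted p = 0.674 with an estimated correlation). The number passing over the list alone was 4 without shMettl3 replicate 2 and 14 without shNC replicate 2. Of the 32 replication-dependent histone genes in the file, only 11 passed the filter on low values and were tested. Camera did not call these 11 (median −0.06, adjusted p = 0.962), which says nothing of the others. Among these, Hist2h2aa1 passed over the list alone (and over all genes in DESeq2, adjusted p = 0.000598), with 66.3 ± 26.7 against 18.2 ± 0.859, and Hist1h1c had 15.2 ± 5.22 against 39.0 ± 17.4. The number of histone genes higher over the list alone was 1 without shMettl3 replicate 1 and 0 without any 1 of the other libraries, and without shNC replicate 2 the log2 fold change of Hist1h1c was −0.80 against −1.36 with all libraries.

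**Figure D2:**
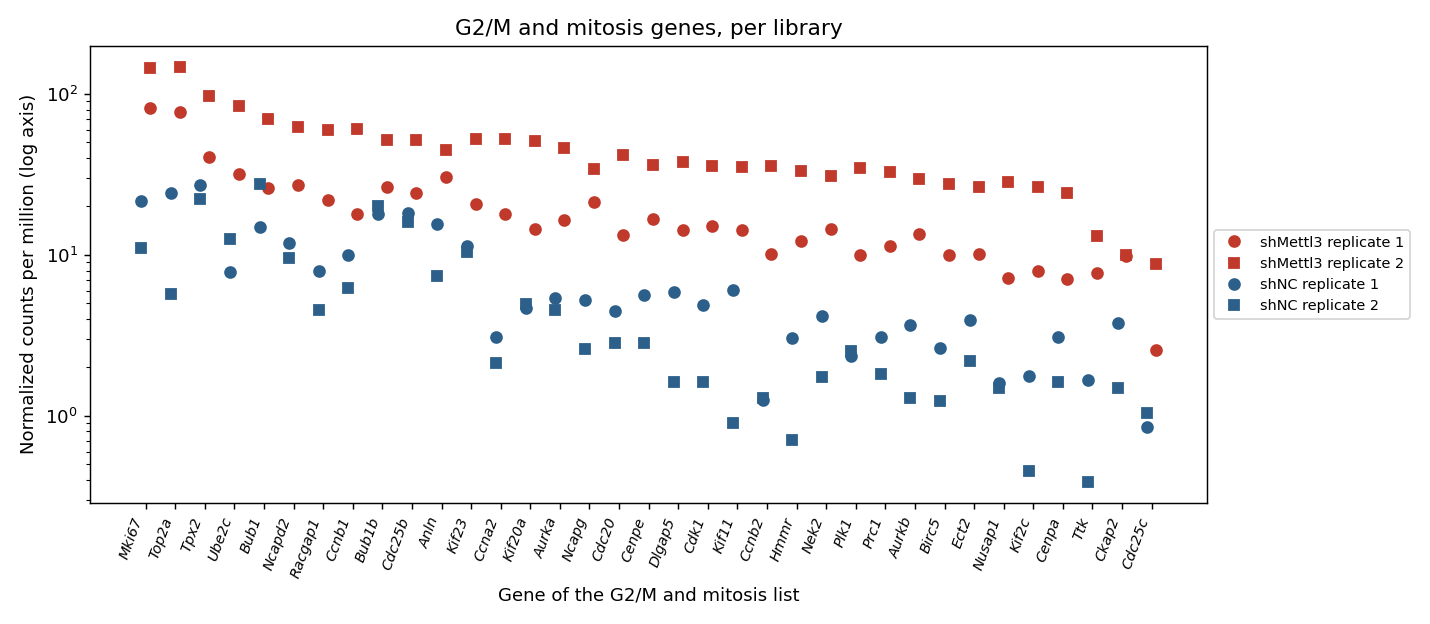
Normalized CPM (log axis) of the 35 tested genes of the G2/M and mitosis list, ordered by their mean in shMettl3, 1 point per library. For 34 of the 35 genes both shMettl3 points (red) lie above both shNC points (blue), and shMettl3 replicate 2 (red squares) lies highest.

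Among inflammatory genes, camera called the chemokine and cytokine lists higher in the knockdown libraries with the preset correlation only, and few of their members passed. Of the 16 tested chemokine genes, 13 had a positive log2 fold change (median 1.25, 2.38-fold), and 2 passed over the list alone with 0 over all genes (5 and 3 in DESeq2). The 2 were Ccl4 and Ccl3, which encode the macrophage inflammatory proteins MIP-1 beta and alpha. Ccl4 had 491 ± 40.0 normalized CPM in shMettl3 and 131 ± 4.08 in shNC (log2 fold change 1.90, SE 0.262), and Ccl3 had 3805 ± 261 against 1404 ± 342 (1.44, SE 0.266). Camera called the list higher (adjusted p = 1.34e-05; adjusted p = 0.674 with an estimated correlation). Without shMettl3 replicate 1 its median was 0.61, and without shNC replicate 1 it was 2.20. The number higher over the list alone was 1 without shMettl3 replicate 1, and 6 without shMettl3 replicate 2 (with 1 lower) or shNC replicate 1. The further gene that DESeq2 called over all genes was Ccl7 (adjusted p = 0.0285), named after its value was seen.

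Of the 15 tested inflammatory cytokine genes, 11 had a positive log2 fold change (median 1.22), and 2 were higher over the list alone with 0 over all genes (5 and 2 in DESeq2). The 2 were Csf3, given above, and Il1rn, which encodes the interleukin-1 receptor antagonist and had 2847 ± 732 against 410 ± 292 (log2 fold change 2.80, SE 0.566). The list was called higher (adjusted p = 0.00203; adjusted p = 0.674 with an estimated correlation). Without shMettl3 replicate 1 its median was −0.27 and its call ended (adjusted p = 0.171), as it did with limma on log2(FPKM + 1) (adjusted p = 0.0510). Without shNC replicate 1, 4 genes were higher and 1 lower over the list alone, and without shMettl3 replicate 1 there were 2 and 1. Of the 23 tested inflammatory effectors and activation markers, 16 had a positive log2 fold change (median 0.73), and 2 passed over the list alone with 0 over all genes. Acod1, which makes itaconate, had 1836 ± 396 against 616 ± 177 (1.58, SE 0.321). Fpr1, a formyl peptide receptor, had 73 and 38 counts against 3 and 2. The list was called higher (adjusted p = 0.0110; adjusted p = 0.674 with an estimated correlation), and not without shMettl3 replicate 1 (adjusted p = 0.696, median 0.11; the median was 1.17 without shNC replicate 1), with limma on log2(FPKM + 1) (0.0692) or among genes with a mean FPKM of at least 5 (0.0691). The number higher over the list alone was 0 without shMettl3 replicate 1 or shNC replicate 2, 1 without shNC replicate 1 and 4, with 1 lower, without shMettl3 replicate 2.

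Interferon-stimulated genes had a positive log2 fold change for 43 of 44 tested members (median 0.72, 1.65-fold). In edgeR's test without a block and in DESeq2, 0 passed over the list alone or over all genes. With a block for the replicate number, edgeR called 25 higher over the list alone and 8 over all genes. No label says that these numbers pair the samples. Oasl1 had 663 ± 313 against 233 ± 147 normalized CPM (log2 fold change 1.51, SE 0.560), and Bst2, tetherin, had 548 ± 93.1 against 274 ± 181 (1.00, SE 0.499). The list was called higher (adjusted p = 1.95e-05; adjusted p = 0.886 with an estimated correlation). The median level of its members relative to their means was 0.91 and −0.18 on the log2 scale in shMettl3 (replicates 1 and 2). In shNC it was 0.52 and −1.33, so the groups overlapped. Between the libraries numbered 1 and between those numbered 2, shMettl3 was higher, by 0.39 and 1.15. A fit without 1 library mixes number with group, so its median also moves with the lower level of replicate 2. Without shNC replicate 2 camera's direction turned to lower (adjusted p = 0.973, median 0.14), and without shMettl3 replicate 1 the median was −0.04 (adjusted p = 0.696). Without shMettl3 replicate 2 or shNC replicate 1 the median was 1.14 or 1.96. Oasl1 was at 0.92 without shMettl3 replicate 1, 2.39 without shNC replicate 1 and 0.99 without shNC replicate 2, and Bst2 at 1.94 without shNC replicate 1 and 0.46 without shNC replicate 2.

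The inflammasome and pyroptosis list was called higher (13 tested, median 0.46, adjusted p = 0.0380; adjusted p = 0.779 with an estimated correlation), with 1 gene over the list alone and 0 over all genes. That gene was Ripk3, a kinase of necroptosis, with 58.6 ± 19.7 against 19.1 ± 4.69 normalized CPM, and Il18 had 27.0 ± 12.9 against 9.63 ± 6.29. This call ended without shMettl3 replicate 1 (adjusted p = 0.565), without shNC replicate 2 (0.112), without the filter on low values (0.105), with a mean FPKM of at least 5 (0.0552) and with limma on log2(FPKM + 1) (0.0779). Its median was 0.21 without shMettl3 replicate 1 and 0.81 without shNC replicate 1, and the number higher over the list alone was 4, with 1 lower, without shNC replicate 1 and 0 without shMettl3 replicate 2 or shNC replicate 2. The log2 fold change of Il18 was 1.49 with all libraries, 0.89 without shMettl3 replicate 1, 2.42 without shNC replicate 1 and 0.96 without shNC replicate 2. The macrophage identity list was called higher (28 tested, 20 positive, median 0.34, adjusted p = 0.00871; adjusted p = 0.674 with an estimated correlation), with 2 genes over the list alone and 0 over all genes. Coro1a, coronin 1A, had 348 ± 22.0 against 92.2 ± 15.8 (log2 fold change 1.92, SE 0.282), and Cd14, the LPS co-receptor, 1450 ± 10.5 against 556 ± 30.3 (1.38, SE 0.238). This call ended without shNC replicate 2 (adjusted p = 0.197) and with limma on log2(FPKM + 0.1) (0.0633) or log2(FPKM + 0.5) (0.0525). The number higher over the list alone was 4 without shNC replicate 1 and 0 without any 1 of the other libraries.

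The glycolysis and hypoxia list was called lower in the knockdown libraries by camera, with the preset correlation only. Of the 29 tested members, 27 had a negative log2 fold change (median −0.59), and 10 had an unadjusted p under 0.05, but 0 passed over the list alone or over all genes in edgeR's test. In DESeq2 10 were lower over the list alone and 1 over all genes. With a block for the replicate number, edgeR called 13 lower over the list alone and 5 over all genes. Vegfa, the vascular endothelial growth factor, had 68.1 ± 1.77 against 173 ± 86.2 normalized CPM (log2 fold change −1.35, SE 0.395), and P4ha2, a collagen prolyl hydroxylase, 0.721 ± 0.427 against 3.70 ± 0.538. The others with an unadjusted p under 0.05, chosen after their values were seen, were Ankrd37, Egln1, Kdm3a, Aldoa, Pdk1, Ero1l, Bnip3 and Ndrg1. Of the 10, Aldoa, an aldolase, is an enzyme of glycolysis, and it had 2642 ± 438 against 4521 ± 965. Camera's adjusted p was 9.4e-08 (adjusted p = 0.674 with an estimated correlation). Without shMettl3 replicate 1 or shNC replicate 2 its median was −0.38 and without shMettl3 replicate 2 it was −1.04, and the call held in each. Without shNC replicate 1, 2 genes were lower over the list alone, and without shNC replicate 2 Vegfa was at −0.71.

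The lysosome and autophagy list was called lower (31 tested, 25 negative, median −0.51, adjusted p = 0.000489; adjusted p = 0.674 with an estimated correlation), with 0 genes over the list alone or over all genes. Gpnmb, a glycoprotein of lysosomes and phagosomes, had 4346 ± 73.5 against 8667 ± 1036 normalized CPM (log2 fold change −0.996, SE 0.209), and Map1lc3a had 9.73 ± 1.91 against 21.6 ± 5.28. The median of the list was −0.08 without shNC replicate 2 (adjusted p = 0.0220) and −0.31 without shMettl3 replicate 1 (adjusted p = 0.0230). Cytosolic ribosomal protein genes were called lower by a small amount (45 tested, 43 negative, median −0.32, adjusted p = 0.00101; adjusted p = 0.886 with an estimated correlation), with 0 genes over the list alone or over all genes. Rps27 had 410 ± 83.3 against 807 ± 37.1 and Rpl23 551 ± 37.8 against 810 ± 78.0. With quantile-normalized values the ribosomal call ended (adjusted p = 0.272), and without shNC replicate 2 the median was −0.20. Alternative activation markers were called lower (9 tested, 7 negative, median −0.74, adjusted p = 0.0380; adjusted p = 0.674 with an estimated correlation), with 0 genes over the list alone or over all genes. That call ended without shMettl3 replicate 1 (adjusted p = 0.0866), shMettl3 replicate 2 (0.0984) or shNC replicate 1 (0.0710), without the filter (0.622), with limma on log2(FPKM + 1) (0.0510) and with quantile-normalized values (0.0792). Its median was −0.28 without shNC replicate 1 (4 positive and 5 negative), −0.47 without shNC replicate 2, and 0.08 without the filter (8 positive and 8 negative of 16). Over the list alone, 3 were lower and 1 higher without shNC replicate 1, and 2 were lower without the filter. Egr2, a transcription factor, had 2.47 ± 1.08 against 11.2 ± 5.06.

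**Figure D3:**
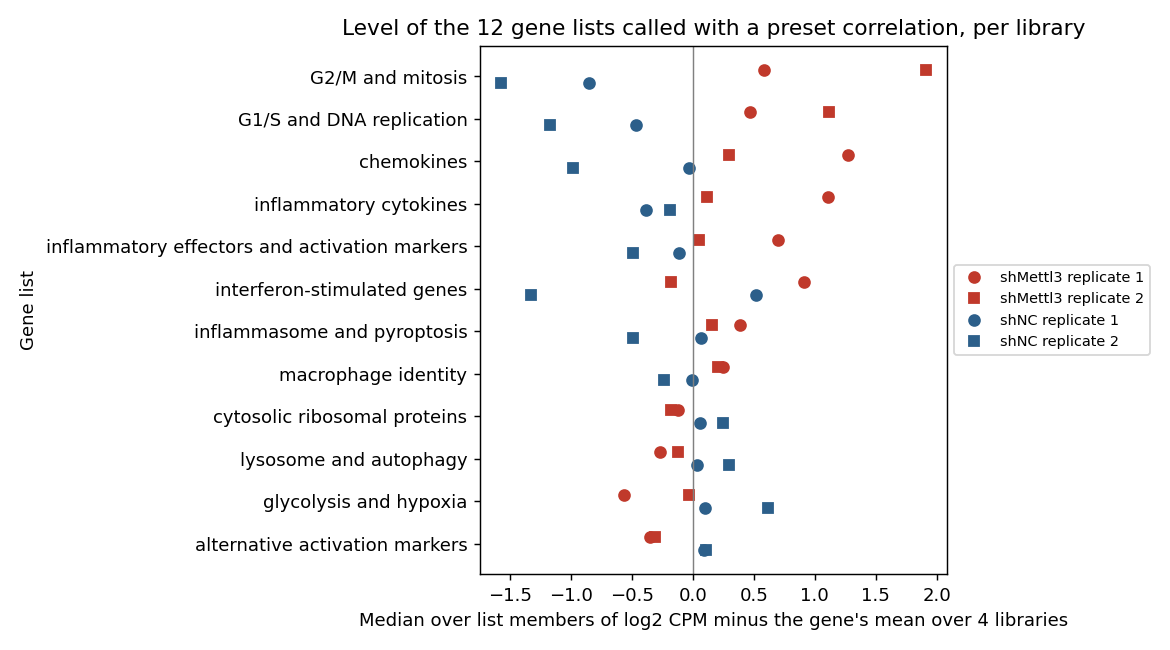
Level of the 12 gene lists called with the preset correlation in each library, as the median over list members of log2 CPM minus the gene's own mean over the 4 libraries (x axis, log2 units), with shMettl3 in red, shNC in blue, circles for replicate 1 and squares for replicate 2. For G2/M and mitosis the shMettl3 libraries lie at 0.58 and 1.91 and the shNC libraries at −0.85 and −1.57, while for interferon-stimulated genes the groups overlap.

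The remaining lists were not called, and 0 of their members passed over all genes in edgeR's test. For feedback inhibitors of inflammatory signalling the median was 0.45 (adjusted p = 0.0739), with Irak3 and Il1rn higher over the list alone. That median was −0.05 and 0.58 without shMettl3 replicate 1 and 2, and 0.20 and 0.31 without shNC replicate 1 and 2. Irak3, a negative regulator of Toll-like receptor signalling, had 137 ± 44.6 against 39.8 ± 11.6 normalized CPM. In TLR4 signalling, Cd14 and Irak3 were higher over the list alone, but the median was −0.11 while the mean was 0.07 and camera's direction was higher (adjusted p = 0.736). The NF-kB pathway had a median of 0.15 (adjusted p = 0.567), with Traf1 at 174 ± 102 against 82.0 ± 22.8 and Ikbke at 166 ± 61.6 against 90.0 ± 30.0. Antigen presentation had a median of 0.20 (adjusted p = 0.489), with members that went both ways. Cd74, the invariant chain of class II molecules, had 403 ± 81.5 against 1139 ± 430, and H2-M3, a class Ib molecule, 40.8 ± 4.51 against 19.1 ± 5.03. Osteoclast differentiation had a median of −0.29 (adjusted p = 0.328), with Mmp9, a matrix metalloproteinase, at 42.0 ± 46.0 against 198 ± 67.6 and Clcn7 at 162 ± 11.6 against 273 ± 0.383. Some of these lists were called with the preset correlation once a library was left out, although with all 4 libraries each of them had an adjusted p = 0.886 with an estimated correlation. Without shMettl3 replicate 2 these were feedback inhibitors (higher, adjusted p = 0.00278), the NF-kB pathway (higher, 0.0304) and osteoclast differentiation (lower, 0.000465). Without shNC replicate 2 feedback inhibitors (higher, 0.000484) and the NF-kB pathway (higher, 0.0328) were called, and without shNC replicate 1 antigen presentation (higher, 0.00277). The number higher over the list alone was 0 without shMettl3 replicate 1 or shNC replicate 2 in both feedback inhibitors and TLR4 signalling, and in the latter also 0 without shNC replicate 1 and 1 without shMettl3 replicate 2. Without shNC replicate 1, 2 feedback inhibitors and 1 antigen presentation gene were lower and 1 antigen presentation gene higher over the list alone. Of osteoclast genes 1 was higher without shMettl3 replicate 1 and 1 lower without shMettl3 replicate 2. Without shMettl3 replicate 1 the log2 fold changes of Traf1 and Ikbke were 0.32 and 0.44, against 1.09 and 0.88 with all libraries. That of Mmp9 was −2.23 with all libraries, −1.41 without shMettl3 replicate 1 and −4.38 without shMettl3 replicate 2. Over all genes DESeq2 called Cd14 and Irak3 (adjusted p = 1.95e-05 and 0.000782), Il1rn (2.99e-05) and Dusp2 (0.0284) higher, and Cd74 (0.00593) and Cish (0.0458) lower. Of these, Dusp2 and Cish, both feedback inhibitors, were named after their values were seen.

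Among metabolic and stress lists, oxidative phosphorylation had a median of 0.08 (adjusted p = 0.736), cholesterol and fatty acid synthesis 0.22 (0.333), cholesterol efflux and lipid storage −0.20 (0.388), and NRF2 antioxidant genes −0.08 (0.588). The median of cholesterol efflux and lipid storage was −0.36 and −0.35 without shMettl3 replicate 1 and 2, and 0.05 and −0.17 without shNC replicate 1 and 2. Abca1, a cholesterol exporter, had 96.3 ± 31.2 against 227 ± 34.4 normalized CPM, and Fabp4, a fatty acid binding protein, 8.88 ± 2.76 against 1.64 ± 1.40. Gstm1, a glutathione transferase, had 30.1 ± 4.41 against 64.8 ± 10.5. The integrated stress response list had a median of −0.25 (adjusted p = 0.345). Aldh1l2, a mitochondrial folate enzyme, was lower over the list alone, at 96.5 ± 18.2 against 462 ± 179, and Chac1 had 66.9 ± 5.40 against 40.8 ± 1.54. Endoplasmic reticulum stress had a median of −0.20 (adjusted p = 0.166), with Ern1, a sensor of unfolded proteins, at 62.4 ± 0.202 against 176 ± 82.7. The p53 targets had a median of −0.12 (adjusted p = 0.556), with Plk2 at 711 ± 245 against 259 ± 5.01 and Trp53inp1 at 14.6 ± 2.18 against 56.2 ± 40.8. With the preset correlation, 4 of these lists were called once a library was left out, although with all 4 libraries each of them had an adjusted p = 0.886 with an estimated correlation. Cholesterol and fatty acid synthesis was called higher without shMettl3 replicate 1 (adjusted p = 2.27e-05) or shNC replicate 1 (0.0294), and lower without shMettl3 replicate 2 (0.0121). Endoplasmic reticulum stress was called lower without shMettl3 replicate 2 (0.00440) or shNC replicate 2 (0.0124). The p53 targets (0.00576) and the integrated stress response (0.0294) were called lower without shNC replicate 1. Over the list alone, 2 cholesterol and fatty acid synthesis genes were lower without shMettl3 replicate 2, and 4 p53 targets and 1 endoplasmic reticulum stress gene without shNC replicate 1, while 1 endoplasmic reticulum stress gene was higher without shMettl3 replicate 1. Without shNC replicate 2 the log2 fold changes of Trp53inp1 and Ern1 were −0.88 and −0.90, against −1.94 and −1.50 with all libraries, and without shNC replicate 1 that of Fabp4 was 3.79 against 2.42. The number lower over the integrated stress response list alone was 1 without shNC replicate 1 and 0 without any 1 of the other libraries. Over all genes DESeq2 called Plk2 higher (adjusted p = 0.00236) and Aldh1l2 (2.4e-06), Ern1 (0.0151), Trp53inp1 (0.0259), Abca1 (0.0260) and Gstm1 (0.0337) lower.

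Apoptosis regulators had a median of 0.02 and a mean of −0.0005, with camera's direction higher (adjusted p = 0.801). Bcl2l11, which encodes the pro-apoptotic protein BIM, had 94.3 ± 17.1 against 49.0 ± 11.97 normalized CPM. Immediate early genes had a median of −0.19 (adjusted p = 0.962), with Dusp6, a MAP kinase phosphatase, at 23.7 ± 0.236 against 10.6 ± 2.69. With the preset correlation they were called lower without shNC replicate 1 (adjusted p = 0.00277, with 1 gene lower over the list alone) and higher without shNC replicate 2 (8.69e-06), and with all 4 libraries they had an adjusted p = 0.989 with an estimated correlation. DESeq2 called 1 member, Egr2, lower over all genes (adjusted p = 0.0264). Splicing factors had a median of 0.08 (adjusted p = 0.489), with Srsf7 at 84.1 ± 12.5 against 49.2 ± 13.8 and U2af1 at 75.0 ± 7.80 against 51.5 ± 4.67. Of the markers of other cell types, 18 were in the file and only S100a8 and Dcn were abundant enough to be tested. S100a8, a gene of neutrophils and monocytes, had 3.35 ± 3.05 against 0.815 ± 0.587, and Dcn, a fibroblast gene, 1.53 ± 0.644 against 2.32 ± 3.10. Without shMettl3 replicate 2 the log2 fold change of S100a8 was 0.55 against 2.04, and that of Dcn ran from −1.54 without shNC replicate 2 to 3.52 without shNC replicate 1. None of the nucleolar RNA host and nuclear retained RNAs of that list was in the table. No list passed with an estimated correlation, in either direction, in a test with few degrees of freedom here.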

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

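Total-count scaling was chosen after the data were seen. Limma on log2(FPKM + 1), the test first planned for FPKM alone, was then made an alternative. The other settings were fixed before the data were examined. The fall of Mettl3 kept its direction and its side of the threshold (unadjusted p) in all 16 alternative settings, with log2 fold changes from −1.57 to −1.33. The count of genes higher in shMettl3 was 0 in edgeR and 211 in DESeq2, and of genes lower 0 in edgeR, 123 in DESeq2 and 1 in edgeR without the filter on low values. The other settings without a block called 0 in each direction. Over all genes, DESeq2 also called 2 inflammatory effectors (Acod1, Fpr1), 2 macrophage identity genes (Coro1a, Cd14) and 1 inflammasome gene (Ripk3) higher, and 2 alternative activation markers (Egr2, Vegfa), 1 lysosomal (Gpnmb) and 1 ribosomal gene (Rps27) lower. The cause of the gap between edgeR and DESeq2 was not tested. The replicate numbers are shared between groups, but no label says that they mark a day or batch, and there were only 2 pairs. Across genes, the deviations of same-numbered libraries from their group means correlated at r = 0.455. With the replicate block, edgeR called 207 genes higher and 108 lower. Of the glycolysis and hypoxia list 13 were then lower over the list alone and 5 over all genes, and of the interferon-stimulated genes 25 and 8 were higher. Over all genes, the block fit also called 22 genes of G2/M, 17 of G1/S, 6 chemokines, 6 macrophage identity genes, 5 cytokines, 2 effectors, 2 inflammasome genes and 1 alternative activation marker higher, and 2 alternative activation markers, 1 effector and 1 lysosomal gene lower. The level of the hypoxia list (log2, shMettl3 minus shNC) differed by −0.67 between the libraries numbered 1 and by −0.65 between those numbered 2, and that of the interferon list by 0.39 and 1.15.

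Of the gene lists, 8 were higher and 4 lower with the preset correlation, against 0 and 0 with an estimated one. The number of lists higher was 4 with limma on log2(FPKM + 0.1) or log2(FPKM + 0.5), and 5 with limma on log2(FPKM + 1). Camera does not use limma's trend or robust prior. The settings without a trend or with a robust prior therefore repeat its values and are not separate checks for lists. Quantile normalization left 2 lists lower. When single libraries were left out, 5 to 10 lists were higher and 3 to 6 lower. In such fits the lone sample of a group is assumed to vary like the other group. They also mix replicate number with group, so a change of direction need not mean that the result rests on the library left out. The calls of G2/M and mitosis, G1/S and DNA replication, chemokines, glycolysis and hypoxia, lysosome and autophagy, and cytosolic ribosomal proteins held without each of the 4 libraries. Of 480 list values under alternatives, those repeats included, 386 kept direction and side of the threshold. With the direction kept, 49 lost the call and 13 gained one. The other 32 turned direction, and some of these lost or gained a call as well. The 76 named genes besides Mettl3 had no call to lose. Of their 1211 values under alternatives, 74 gained a call (73 of them with DESeq2 or the block) and 24 turned direction. Leaving out 1 library moved the log2 fold change of 29 of the 77 named genes, Mettl3 not among the 29, by over 1.5 times or across 0. The number of effectors higher over the list alone was 0 with limma on log2(FPKM + 0.1), log2(FPKM + 0.5), log2(FPKM + 1) or quantile-normalized values and with a mean FPKM of at least 5, and that of G2/M genes was 22 of 23 tested with a mean FPKM of at least 5.

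Some log2 fold changes turned sign. Total-count scaling, which leaves out TMM, gave a median of 0.0691 over all genes against −0.0086 in the main fit. Mettl14 and Cbll1 rose with it. The causes of the other turns were not tested. Mettl14 was at 0.0177 and 0.0173 with limma on log2(FPKM + 0.1) and log2(FPKM + 0.5), at 0.0168 with limma on log2(FPKM + 1), without a trend or with a robust prior, and at 0.0323 with total-count scaling. Wtap was at 0.0134, 0.0132 and 0.0130 in the same limma fits, and Cbll1 at 0.0108 with total-count scaling. Dcn was at 0.537 and 0.0669 with limma on log2(FPKM + 0.1) and log2(FPKM + 0.5), and at 0.221 with the block. Leaving out single libraries gave −0.31 to 0.12 for Cbll1, −0.22 to 0.0998 for Mettl14, −0.0155 to 0.17 for Virma, −0.26 to 0.0175 for Wtap, −0.16 to 0.957 for Fto, −0.87 to 0.0562 for Ythdf3 and −1.54 to 3.52 for Dcn.

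The adjusted p of lists that turned direction ranged, over the fits that left out a library, as follows, with fewer samples in each fit. It was 0.355 to 0.745 for m6A readers, 0.0304 to 0.679 for the NF-kB pathway and 0.607 to 0.965 for TLR4 signalling. It was 6.93e-17 to 0.973 for interferon-stimulated genes, 0.00277 to 0.745 for antigen presentation and 0.000465 to 0.646 for osteoclast differentiation. For oxidative phosphorylation it was 0.412 to 0.821, for cholesterol and fatty acid synthesis 2.27e-05 to 0.867, and for p53 targets 0.00576 to 0.821. The integrated stress response ran from 0.0294 to 0.819, endoplasmic reticulum stress from 0.00440 to 0.696 and NRF2 genes from 0.113 to 0.965. Apoptosis regulators ran from 0.405 to 0.906, immediate early genes from 8.69e-06 to 0.745, splicing factors from 0.0581 to 0.965 and histones from 0.670 to 0.880. Immediate early genes also turned at 0.993, 0.966 and 0.972 in the limma fits on log2(FPKM + 0.1), log2(FPKM + 0.5) and log2(FPKM + 1) (0.972 too without a trend or with a robust prior), at 0.771 with quantile normalization, 0.887 without a filter and 0.880 with a mean FPKM of at least 5. Histones turned at 0.997 with limma on log2(FPKM + 0.1) and 0.702 without a filter. The median log2 fold change of all genes stayed between −0.0416 and 0.0786 in every setting. At these library totals, depth was not limiting for abundant genes, but genes with few control reads, such as Urah, have uncertain folds.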

Other observations

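Genes in the next 2 paragraphs were chosen after their values were seen. Both knockdown libraries lay below both controls for 2268 of the 10291 genes tested, and those given first are single examples outside the fixed lists, not tested as a group. Psap, which encodes saposins, had 1680 ± 126 normalized CPM in shMettl3 and 3748 ± 1282 in shNC (SD, n = 2 each), Tpp1, a lysosomal peptidase, 363 ± 31.6 against 690 ± 61.0, and Dpp7, another peptidase, 55.6 ± 0.650 against 138 ± 15.7. Naglu and Arsa, which encode enzymes of glycan and sulfatide breakdown, had log2 fold changes of −1.02 and −0.90. Lgals3, galectin-3, had 1407 and 1394 against 2372 and 2931. Their adjusted p in edgeR's test ran from 0.304 to 0.355, so none passed. Among cytoskeletal genes, Actb had 3385 and 2990 in shMettl3 against 1423 and 1248 in shNC (log2 fold change 1.26, adjusted p = 0.304).

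Other single examples varied widely between the libraries of each group. Rsad2, an antiviral protein, had 1029 and 63.5 normalized CPM in shMettl3 replicates 1 and 2 and 319 and 14.0 in shNC replicates 1 and 2. In the same order, Ccl5 had 1346, 142, 1426 and 125, Il6 had 104, 1.91, 16.0 and 0, Il1b had 338, 57.3, 145 and 4.14, and Cfb, complement factor B, had 254, 34.1, 218 and 2.01. Adamtsl4 went the other way, with 8.69, 829, 14.2 and 598, as did the macrophage growth factor receptor gene Csf1r, with 107, 275, 105 and 261, and S100a4, with 97.4, 374, 90.7 and 211. Hspa8, a heat shock protein gene, had 5628, 1061, 4168 and 2285.

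Of the tests below, those of gene length and expression level were set before their results were seen, and those of left-out libraries and of gaps between libraries after. The higher level of cell cycle genes in shMettl3 was weighed first. Removing a smooth trend of all genes on length and expression level left the median log2 fold change of the mitosis list at 2.68, which argues against that trend as the whole cause. Leaving out any 1 library left the median at 1.92 or more and the list's call with the preset correlation in place (adjusted p = 0.674 with an estimated correlation), although 0 of 35 genes passed over the list alone without shNC replicate 2. A growth state of the dishes that is unrelated to the knockdown may also give this pattern: the smallest gap between groups was 1.08 times the largest gap within a group, so this and an effect of the knockdown cannot be told apart with 2 libraries per group.

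The lower call of the glycolysis and hypoxia list was weighed next. After removal of the trend on length and level the median log2 fold change was −0.53, and without any 1 library the median stayed at −0.38 or lower, with a highest adjusted p of 0.000707, which argues against either as the whole cause of the lower median. These p-values use the preset correlation, and the list was not called with an estimated one (adjusted p = 0.674). The list's levels were −0.57 and −0.03 in shMettl3 and 0.10 and 0.62 in shNC (log2, replicates 1 and 2). The smallest gap between groups was thus 0.251 times the largest gap within a group. That smallest gap lay between libraries of different numbers, shMettl3 replicate 2 and shNC replicate 1. Between the libraries numbered 1 and between those numbered 2, shMettl3 was lower, the differences being −0.67 and −0.65. The gap within groups may come from single dishes or from something that libraries of one number share, which the labels do not say, so a difference between dishes and an effect of the knockdown cannot be told apart.

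The higher call of the interferon-stimulated list was weighed last; it too was lost with an estimated correlation (adjusted p = 0.886). Without shNC replicate 2 the call ended, the list's median was 0.14 and camera's direction turned to lower. The list's levels were 0.91 and −0.18 in shMettl3 and 0.52 and −1.33 in shNC (log2, replicates 1 and 2). Replicate 2 was thus lower in both groups, and shMettl3 was higher within each number, by 0.39 and 1.15. Without shNC replicate 2, both shMettl3 libraries are set against shNC replicate 1 alone, so that fit mixes number with group. The low level in shNC replicate 2 may come from that dish or from something that libraries of one number share. The median stayed at 0.70 after removal of the trend on length and level, which argues against that trend. The call also ended without shMettl3 replicate 1 (adjusted p = 0.696), and an effect of the knockdown on this list stays an open hypothesis.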
